A study of Mus musculus with 12 samples.

How the data were processed

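RNA from 12 mouse samples was measured on 1-colour arrays of 29922 probes, with 3 arrays in each of 4 groups. Per the labels, 5 ug of total RNA from muscle was amplified and labelled with Cy5 for each array, and the treated mice received 2.5 nmol mcIRBP. The deposited array files hold 2 columns per probe, a raw intensity and a normalized intensity, both on a linear scale. The authors' processing notes name limma without a version, and any background step behind the raw intensity is not given in the sources used here. The files hold no flags, no negative controls, no probe coordinates and no scan dates.

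The deposited normalized intensity had the same rank order as the raw intensity on every array (lowest Spearman rho 1). Within a tolerance of 0.01, at least 96.6% of its values were whole multiples of 1/9 on the normal arrays and at least 96.5% were whole multiples of 1/10 on the diabetic arrays. The sorted values were nearly the same within a disease state and differed between the states, with medians of 62.9 to 63.2 on the normal arrays and 40.0 to 41.0 on the diabetic arrays. The authors had thus normalized the arrays of each disease state as a separate set. For multiples of 1/18 and 1/20 the shares were 99.98% and 100%. Multiples of 1/9 and 1/10 would arise from averages over 9 and 10 arrays, and sets of 18 and 20 are not excluded. Only 6 arrays of each state are in this series, so these values may depend on arrays not used here. The deposited table of all samples was identical to these columns (largest difference 0). For this reason the raw intensity was used here, and the deposited normalized intensity served as an alternative only for effects within a disease state, apart from a planned check of the Y-linked gene Eif2s3y.

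Raw intensities of all 12 arrays were corrected with the normexp method (offset 50), quantile normalized together and taken to log2 in limma 3.58.1 under R 4.3.3 with statmod 1.5.0. A model with 1 mean per group left 8 residual degrees of freedom, and limma's moderated test was applied to all 29922 probes with Benjamini-Hochberg adjustment at 0.05. The comparisons were mcIRBP against mock in normal mice, mcIRBP against mock in diabetic mice, the difference between these effects, their mean, and diabetic mock against normal mock. A gene "rose", "fell" or "changed" below where its adjusted p was under the threshold. Log2 fold changes are differences of group means (a value after "at" behind a gene is its log2 fold change in the comparison named), with the standard error (SE) from the model, and group values are given as mean with SD over 3 arrays. The limma p-values of probes rest on the spread between arrays within groups, pooled over the 4 groups. This spread may be partly technical, since the labels do not say whether the 3 arrays came from 3 mice. The camera p-values of gene lists, described below, compare a list's genes with other genes and rest on a preset correlation between genes.

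The floor of each array was the mode of its log2 raw intensities, and a probe counted as above the threshold when it exceeded the mode by 5 SD of the values mirrored below it. Where no array of 1 group was above its threshold, the fold is given as a lower bound against the lowest intensity above it ("at least"), and no fold is given where that bound was under 1 or both groups were below. The test, the ranking of genes and the medians of lists used fitted values, which are no bounds. Where some arrays of a group were above the threshold, the fitted value is given. For the difference of effects and for some medians a second value sets such groups to the threshold, with an effect of 0 where both groups were below it or the sign turned. Of the probes, 21020 had 1 gene symbol, 8902 had none and 0 had several. The 16675 distinct symbols included 16633 found in the RefSeq annotation of the mouse genome build GRCm38 as a symbol or a synonym, from which gene positions were taken. The number of arrays limits the precision.

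The named genes of each comparison were the 10 with the largest rise and the 10 with the largest fall among called probes with a symbol, up to 4 members with the lowest p of each called gene list, and fixed genes of insulin action. All comparisons other than the difference of effects and the mean effect also required that the 3 arrays of each group did not overlap. Irs2 and Gys1 were among the fixed genes and had no probe. No genes were named for the mean effect. Among the named genes 25 had another probe on the array, and of 31 calls of such genes 10 were shared, in the same direction, by all their other probes. Largest changes were taken over all probes, and list members and fixed genes by the probe with the highest mean.

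Gene lists for pathways and cell types were written before the data were examined (36 lists, of which 34 had at least 5 measured members). Each gene was represented by 1 probe (16637 genes), and each list was tested with camera at its preset correlation of 0.01. The same lists were tested with an estimated correlation and with fry, which asks whether a list's genes move on balance one way and does not compare them with other genes. A further 17 lists of tissue markers were written after the genes with the largest changes had been seen. For the liver, epididymis and adipose tissue lists, results for genes that had not been seen are given separately.

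Alternatives chosen before the data were examined were median scaling, no background correction, the deposited normalized intensity, array weights, a block by replicate number, fits on the compared groups alone, and leaving out each array. The planned filter on dim probes needed flags or negative controls. After the data had been seen it was replaced by a filter that kept the 10764 probes above the threshold on at least 3 arrays. A fit without 2 arrays that stood apart from their groups and a fit without the 144 probes of liver, epididymis and adipose list genes were also added after the data had been seen. The fit was tested on simulated data with 200 changed probes, where it called 81.0% of 2-fold and 96.2% of 4-fold changes, with 5.42% false calls among those called. The simulated arrays all had the same spread per probe and independent probes, unlike the real arrays. These shares therefore need not hold for the real comparisons.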

Results

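Gene expression was measured in tissue labelled as muscle from BALB/c mice that had been treated with mcIRBP, an insulin receptor-binding protein from bitter melon (Momordica charantia), or left without it as mock controls. The 12 arrays fell into 4 groups of 3: normal mock, normal mcIRBP, diabetic mock and diabetic mcIRBP. The normal mice were labelled female and the diabetic mice male, so disease state, sex and the authors' normalization set fell on the same arrays. Between 2551 and 3824 of the 29922 probes lay above the floor threshold on the normal mock arrays, 5160 to 8248 on the normal mcIRBP arrays, 9986 to 12212 on the diabetic mock arrays and 4302 to 7749 on the diabetic mcIRBP arrays. The mean Pearson r between arrays of a group, across probes, was 0.902 for normal mock, 0.880 for normal mcIRBP, 0.984 for diabetic mock and 0.950 for diabetic mcIRBP. Between groups it was 0.788 for normal mock with normal mcIRBP, 0.902 for normal mcIRBP with diabetic mock and 0.826 for diabetic mock with diabetic mcIRBP. The Y-linked gene Eif2s3y was above the threshold on 6 of 6 diabetic arrays and 0 of 6 normal arrays, at least 1.65-fold higher on average. The Y-linked genes Jarid1d, Uty, Zfy1 and Usp9y were below the threshold on all 12 arrays, and Xist, which is expressed from the inactive X chromosome, had no probe.

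Markers of skeletal muscle were mostly at the floor, while markers of adipose tissue, liver and epididymis were bright in some groups. Of 42 skeletal muscle genes, 1 was above the threshold on all 3 normal mock arrays, 1 on all 3 normal mcIRBP arrays, 9 on all 3 diabetic mock arrays and 2 on all 3 diabetic mcIRBP arrays. Of 29 adipose tissue genes, the same counts were 22, 25, 27 and 14. Of 67 liver genes they were 54, 9, 14 and 5, and of 36 epididymis genes 0, 0, 25 and 32. Among the 15 brightest genes of the normal mock arrays were Alb, which encodes serum albumin, with a mean log2 intensity of 13.77 ± 0.07 (SD, n = 3), and Ttr, which encodes the plasma carrier transthyretin, with 13.09 ± 0.50 (SD, n = 3). The adipokine gene Adipoq had 12.69 ± 0.32 (SD, n = 3) on the same arrays and 13.89 ± 0.48 (SD, n = 3) on the normal mcIRBP arrays. Of 23 housekeeping genes, 15, 16, 20 and 15 were above the threshold on all 3 arrays of the groups in the order above. For brown fat the counts were 1, 3, 5 and 2 of 16 genes, for lymphoid tissue 2, 6, 9 and 6 of 23, for uterus and smooth muscle 0, 2, 9 and 5 of 15, and for skin 1, 0, 5 and 4 of 12. They were 0, 0, 4 and 2 of 16 for ovary, 1, 1, 3 and 3 of 18 for kidney, and 0, 0, 3 and 1 of 18 for brain. For small intestine they were 1, 1, 3 and 2 of 14, for heart 0, 0, 1 and 0 of 17, and for seminal vesicle 0, 0, 2 and 1 of 12.

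**Figure D1:**
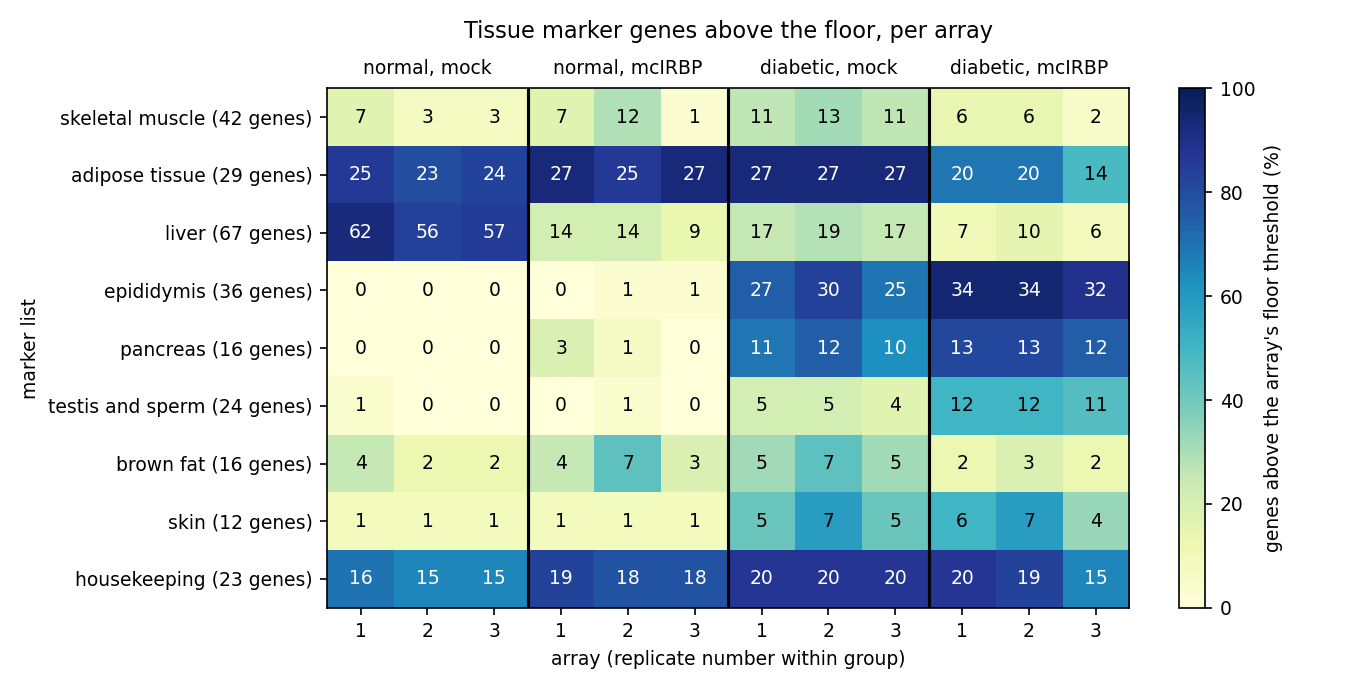
Number of genes of 9 tissue marker lists above the floor threshold on each of the 12 arrays (columns, replicate number within group), with the colour giving the percentage of the list's measured genes. Liver markers were above the threshold mainly on the 3 normal mock arrays (56 to 62 of 67 genes), epididymis markers on the 6 diabetic arrays (25 to 34 of 36), and few skeletal muscle markers were above it on any array (1 to 13 of 42 genes).

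**Figure D2:**
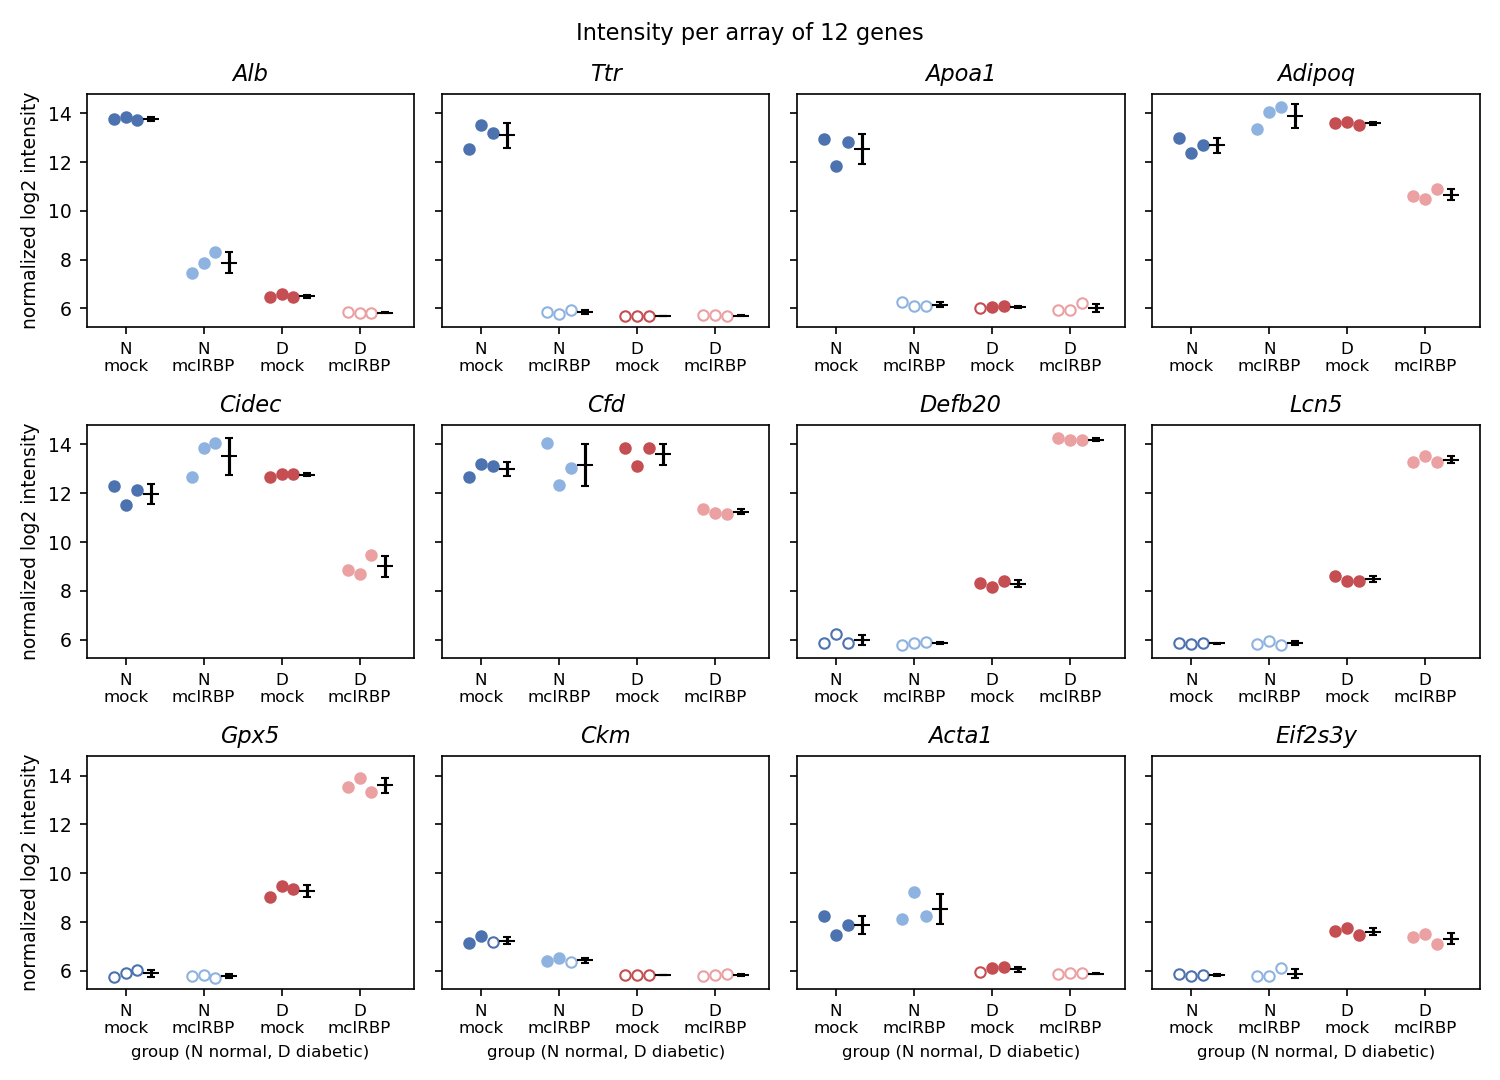
Normalized log2 intensity of 12 genes on each array (points, filled where the probe was above the array's floor threshold and open where not), with the mean and SD of the 3 arrays of each group (black). Alb, Ttr and Apoa1 stood far above the floor on the normal mock arrays, Defb20, Lcn5 and Gpx5 were brightest on the diabetic mcIRBP arrays, and the muscle creatine kinase gene Ckm was at or near the floor on all arrays.

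The comparison of normal mcIRBP with normal mock mice asked what the protein changed in animals without diabetes. Genes of the liver's secreted plasma proteins were lower on the mcIRBP arrays, by amounts far larger than any rise. Ttr (probe mMC011315, chromosome 18, 20664209 to 20674326) fell at least 106-fold, from a mean log2 intensity of 13.09 ± 0.50 (SD, n = 3) to below the threshold (adjusted p = 4.56e-09 in limma). Apoa2, a protein of high density lipoprotein, fell at least 93.0-fold, and Hamp, which encodes the iron hormone hepcidin, at least 60.8-fold. Ccl12, a chemokine that attracts monocytes, rose at least 3.44-fold, and Cav1, the main protein of caveolae, rose from 10.45 ± 0.28 to 12.39 ± 0.27 (log2 intensity, SD, n = 3). The other large falls were of Apoa1, Serpinc1 and Fabp1, and of Serpina1e with a log2 fold change of -6.56 (above the threshold on 1 of 3 normal mcIRBP arrays), Ahsg with -5.95 (2 of 3), Alb with -5.89 and Apoc3 with -5.51. For the bile and fatty acid binding protein gene Fabp1 the fall was at least 50-fold, for Apoa1 at least 72.1-fold and for the antithrombin gene Serpinc1 at least 53.2-fold. The adjusted p of these 10 falls ran from 1.60e-11 to 6.14e-08.

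The 10 largest rises had smaller folds. Cav1 had a log2 fold change of 1.94 (SE 0.18, adjusted p = 8.59e-05). Ccl12 had an adjusted p of 0.0254, Pim3, a serine/threonine kinase, a log2 fold change of 2.39, and Xbp1, a transcription factor of the unfolded protein response, 2.27. The tight junction gene Cldn5 rose at least 2.60-fold and the interferon-inducible gene Ifi205 at least 2.12-fold. Herc2 had a log2 fold change of 2.12, H2-Ea 2.05, Id1 2.0 and 5730469M10Rik 1.98. Under at least 1 of 21 alternatives each of these 9 rises lost its call, while Cav1 kept it under all of them.

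Cholesterol synthesis genes were lower on the normal mcIRBP arrays, and genes of inflammation and macrophages were higher. The fitted medians were -0.69 for cholesterol synthesis, 0.71 for macrophage markers and 0.38 for inflammatory genes. For diabetic mock against the same normal mock arrays, without mcIRBP, they were -0.85, 0.69 and 0.0099. For the cholesterol and macrophage lists a peculiarity of the normal mock arrays thus cannot be told apart from an effect of mcIRBP. The same holds for the extracellular matrix (0.23 and 0.26), endothelial (0.23 and 0.24), ribosomal (0.23 and 0.24) and fast fibre (-0.19 and -0.33) lists below. It is not excluded for inflammatory genes. Of these, 8 were above the threshold on all 3 normal mock, 18 on all 3 normal mcIRBP and 21 on all 3 diabetic mock arrays. Of 17 measured cholesterol synthesis genes, 8 fell, 0 rose and 9 did not pass (adjusted over the list alone, 9 fell and 1 rose), with a camera adjusted p of 3.07e-06 that stayed under the threshold with an estimated correlation. They included Idi1, which makes the isoprenoid building block, with a log2 fold change of -2.92 (above the threshold on 1 of 3 normal mcIRBP arrays), Fdps, which makes farnesyl diphosphate, with -2.51, Sc4mol with -1.58 (1 of 3) and Tm7sf2 with a fall of at least 2.45-fold. Of 32 genes of inflammatory cytokines and NF-kB targets, 9 rose and 0 fell (adjusted over the list alone, 14 rose), with an adjusted p of 2.42e-05 that also stayed under it. The chemokine gene Ccl2 had a log2 fold change of 1.36 and Ccl4 rose at least 1.09-fold. The bacterial lipoprotein receptor gene Tlr2 and Ptgs2 passed without a fold, the last below the threshold on all 6 arrays. Of 15 macrophage markers, 5 rose and 0 fell (adjusted over the list alone, 8 rose), with an adjusted p of 0.000175. The list had adjusted p = 0.164 with an estimated correlation (range over the alternatives 6.01e-05 to 0.164). Cd14 had a log2 fold change of 0.97 and Lyzs 0.88, while Emr1, the F4/80 antigen, and Cd163 passed without a fold. Of 33 extracellular matrix genes, 2 rose and 0 fell (adjusted over the list alone, 9 rose), with an adjusted p of 0.00332. That list too had adjusted p = 0.164 with an estimated correlation (range 2.22e-05 to 0.164). These were Col5a1, a fibrillar collagen, without a fold and the collagen chaperone gene Serpinh1 with 0.75, while Col1a1 had an adjusted p of 0.0567 and Timp1 a log2 fold change of 0.41 (adjusted p = 0.0647). With groups below the threshold set to it, the median of the list was 0.026 (fitted 0.23), that of macrophage markers 0.16 (fitted 0.71) and that of inflammatory genes 0 (fitted 0.38).

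A further 3 lists passed with an adjusted p of 0.0489 each and lost the call under several alternatives. Of 12 endothelial markers, 4 rose and 0 fell (adjusted over the list alone, also 4). Members included Cldn5, Esam1 with a log2 fold change of 1.06, Flt1, which rose at least 1.32-fold, and Tek without a fold. Of 22 ribosomal protein genes, 4 rose and 1 fell (adjusted over the list alone, the same counts of 4 and 1). Members included Rps21 at 1.40, Rps19, which rose at least 1.0-fold, and Rpl38 and Rps24 without a fold. The fast fibre list was lower, and of its 15 contractile genes 3 fell and 1 rose (adjusted over the list alone, 5 fell and 1 rose). Members included the myosin light chain gene Mylpf at -1.04, the calcium pump gene Atp2a1 at -0.78 and Tpm1, which rose at least 1.19-fold, while Mybpc2 was below the threshold on all 6 arrays. With an estimated correlation the adjusted p was 0.164 for both the endothelial and the ribosomal list and 0.422 for the fast fibre list. Over all alternatives it ranged from 0.00173 to 0.269 for endothelial markers, from 6.10e-06 to 0.164 for ribosomal proteins and from 0.00379 to 0.463 for fast fibre genes. Other probes of Rpl38, Rps19, Rps24 and Ptgs2 were not called.

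None of the fixed genes of insulin action changed in normal mice. The insulin receptor gene Insr (probe mMC002044, chromosome 8, 3150922 to 3279649) was below the threshold on all 6 arrays (adjusted p = 0.453), as were Irs1 (adjusted p = 0.493) and Ppargc1a (adjusted p = 0.547). The glucose transporter gene Slc2a4 (GLUT4) was below it on all normal mock arrays (adjusted p = 0.538). Pik3r1 had a log2 fold change of 0.08 (adjusted p = 0.865), Hk2 0.34 (adjusted p = 0.216) and Pdk4 0.57 (adjusted p = 0.331). Akt2 had -0.34 (adjusted p = 0.499), with the opposite sign under median scaling and by 2 other probes. Of 48 insulin receptor signalling genes, 3 rose and 0 fell (adjusted over the list alone, 4 rose; camera adjusted p = 0.212), and of 27 genes of GLUT4 traffic and glucose uptake 3 rose and 0 fell (adjusted over the list alone, 5 rose; camera adjusted p = 0.143). In all, 1845 of 29922 probes were called, 1034 higher and 811 lower, and 6394 had an unadjusted p under 0.05. On the same arrays 59 of 67 liver markers fell and 0 rose, with a median log2 fold change of -3.23 (-2.90 with groups below the threshold set to it), while 3 of 29 adipose tissue genes rose and 2 fell. Of the genes that had not been seen, 36 of 44 liver markers fell and 0 rose, and 2 of 19 adipose tissue genes rose and 1 fell. The count of called probes fell to 292 under median scaling (31 higher, 261 lower), 520 in a fit of these 6 arrays alone (152 higher, 368 lower) and 616 with array weights (145 higher, 471 lower), and rose to 2813 without normal mock replicate 1 (1299 higher, 1514 lower). Falls also outnumbered rises with the deposited normalized intensity (468 higher, 544 lower), with a block by replicate number (586 and 599) and without normal mock replicate 2 (831 and 1085) or 3 (946 and 1171).

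The comparison of diabetic mcIRBP with diabetic mock mice asked what the protein changed in diabetic animals. Genes known from the epididymis, the duct in which sperm mature, were far higher on the mcIRBP arrays, and genes of fat storage were lower. Defb20, a beta-defensin of the epididymis (probe mMC002960, chromosome 2, 152477063 to 152479934), rose from 8.30 ± 0.14 to 14.20 ± 0.05 (log2 intensity, SD, n = 3), a log2 fold change of 5.90 (SE 0.10, adjusted p = 3.46e-10). Rnase9, a secreted epididymal protein, rose with a log2 fold change of 5.35, and Lcn8, a lipocalin, with 5.26. Car3, a carbonic anhydrase abundant in fat and muscle (probe mMC022149, chromosome 3, 14863538 to 14872381), fell from 13.12 ± 0.16 to 8.70 ± 0.29 (log2 intensity, SD, n = 3), a log2 fold change of -4.42 (SE 0.53, adjusted p = 0.000501), and by another probe it had -3.19 (adjusted p = 0.000306). Cidec, a lipid droplet protein, had -3.76 (SE 0.36, adjusted p = 0.000103). The other large rises were of 9230104L09Rik with a log2 fold change of 5.57, Ces7 with 5.55, BC048679 with 5.49, Cst12 with 5.30, Spag11 with 5.28, Defb12 with 5.19 and Spint4 with 5.16. The lipogenic regulator gene Thrsp fell at least 13.7-fold. The other large falls were of the retinol carrier gene Rbp4 with -3.81, Pck1, which feeds glycerol synthesis in fat, with -3.70, Serpina3c with -3.64, 6530401D17Rik with -3.57, S3-12, the lipid droplet coat protein perilipin 4, with -3.52, D430015B01Rik with -3.50 and Prkar2b with -3.46. These 20 probes kept their calls under all alternatives run for them (20 or 21). Other probes of these genes gave 3.36 for Ces7, -3.09 for Pck1, -0.90 for 6530401D17Rik, -0.89 for Prkar2b (adjusted p = 0.0765) and -0.24 for D430015B01Rik (adjusted p = 0.352). On the same arrays 33 of 36 epididymis genes rose and 0 fell, with a median log2 fold change of 4.28, while 0 of 29 adipose tissue genes rose and 23 fell, with a median of -2.65. Of the genes that had not been seen, 14 of 17 epididymis genes rose and 0 fell, and 14 of 19 adipose tissue genes fell and 0 rose.

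Lists of fat cells and several lists of energy metabolism fell on the diabetic mcIRBP arrays, while glycolysis was not called (19 genes, fitted median -0.12). Of 13 adipocyte markers, 9 fell and 0 rose (adjusted over the list alone, 11 fell), with a median log2 fold change of -2.36 and a camera adjusted p of 4.86e-12. Adipoq had -2.93, and Pparg, the master regulator of fat cell formation, fell at least 2.89-fold. Of 35 genes of fatty acid uptake and oxidation, 17 fell and 0 rose (adjusted over the list alone, 22 fell; adjusted p = 2.16e-12). Members included the lipoprotein lipase gene Lpl at -3.07, Angptl4 at -2.74, Acsl1 at -2.01 and Echs1 at -1.52. Of 25 genes of the TCA cycle and pyruvate dehydrogenase, 10 fell and 0 rose (adjusted over the list alone, 16 fell; adjusted p = 4.56e-10). Members included Idh3g at -2.07, Sdhb at -2.06, the citrate synthase gene Cs at -1.78 and Idh3b at -0.97. Of 63 genes of oxidative phosphorylation, 6 fell and 0 rose (adjusted over the list alone, 9 fell; adjusted p = 3.91e-08), among them Cox8b at least 2.59-fold, Uqcrc2 at -1.24 and Cox6a1 at -1.21. Of 19 lipogenesis genes, 9 fell and 3 rose (adjusted over the list alone, 10 fell and 3 rose; adjusted p = 0.000329). Members included the malic enzyme gene Me1 at -2.70, the fatty acid desaturase genes Scd1 at -2.65 and Fads2 at 1.59, and Lpin1 at -2.26. Of 26 genes of muscle atrophy and FoxO targets, 8 fell and 1 rose (adjusted over the list alone, 12 fell and 1 rose; adjusted p = 1.66e-05). The members of that list with the lowest p were Pdk4, which shuts off pyruvate dehydrogenase, the mTOR inhibitor gene Ddit4 at -1.36, Eif4ebp1 at -2.46, and the autophagy gene Gabarapl1 at -0.96.

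Extracellular matrix, macrophage and endothelial genes fell as well, and epidermal markers rose. Other lists of cells found in many tissues were not called as lists. Smooth muscle and pericyte markers rose in 2 and fell in 3 of 12 (adjusted p = 0.611), neutrophil markers rose in 1 and fell in 1 of 10 (adjusted p = 0.910), lymphocyte markers had 0 calls among 12 (adjusted p = 0.143), and nerve and Schwann cell markers rose in 1 and fell in 0 of 10 (adjusted p = 0.649). On all 3 diabetic mock arrays 2 of the 12 lymphocyte markers and 2 of the 10 nerve markers were above the threshold, so few could fall. Of 33 extracellular matrix genes, 9 fell and 0 rose (adjusted over the list alone, 16 fell; adjusted p = 6.20e-09). Members included Nid1 at -1.74, Sparc at -0.97, Serpinh1 at -0.73 and Col15a1, which fell at least 1.09-fold. Of 15 macrophage markers, 9 fell and 0 rose (adjusted over the list alone, 11 fell; adjusted p = 1.40e-07). Members included the mannose receptor gene Mrc1 at -1.88, Cd14 at -1.79, Lyzs at -1.27 and Cd163, which fell at least 1.01-fold. Of 12 endothelial markers, 6 fell and 0 rose (adjusted over the list alone, 7 fell; adjusted p = 2.51e-06), with Cdh5, the junction protein VE-cadherin, at -1.46, while Vwf fell at least 1.17-fold, Flt1 at least 1.29-fold and Tek without a fold. Of 32 genes of inflammatory cytokines and NF-kB targets, 2 fell and 0 rose (adjusted over the list alone, also 2; adjusted p = 0.0104), the acute phase gene Saa3 at -1.90 and Tlr2 without a fold, while Socs3 had -1.09 (adjusted p = 0.134) and Ccl2 -0.70 (adjusted p = 0.0641). Of 12 epidermis markers, 4 rose and 0 fell (adjusted over the list alone, 5 rose; adjusted p = 0.000462). Members included the keratin gene Krt14 at 2.56, Perp at 1.55, the desmosome gene Dsp at 1.20 and Lor at 0.39. Ribosomal protein genes rose in 6 and fell in 1 of 22 (adjusted over the list alone, 9 and 1; adjusted p = 0.00283). Members included Rps21 at 1.54, Rps19, which fell at least 1.16-fold, and Rpl22 at 0.60 and Rpl31 at 0.57, of which the last pair had the opposite sign under median scaling. Unfolded protein response genes rose in 6 and fell in 2 of 25 (adjusted over the list alone, 9 and 2; adjusted p = 0.0104). Members included Sdf2l1 at 1.66, Herpud1 at 0.70, Asns at -2.17 and Dnajb9 at 0.77, which had the opposite sign under median scaling. Under median scaling both these list calls ended, with an adjusted p of 0.520 for ribosomal proteins (range over the alternatives 1.07e-05 to 0.520) and 0.761 for the unfolded protein response (range 0.000524 to 0.761).

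A further 4 lists were called lower with few called members. Of 27 autophagy genes, 2 fell (adjusted over the list alone, 3 fell; adjusted p = 0.0179), Gabarapl1 and Atg3, the latter at -0.89, while Ulk1 had -0.30 (adjusted p = 0.108) and Bnip3 an adjusted p of 0.0661. Of 16 glycogen metabolism genes, 4 fell (adjusted over the list alone, 6 fell; adjusted p = 0.0179), and the list had adjusted p = 0.143 with an estimated correlation (range over the alternatives 0.0105 to 0.147). The 4 were the phosphorylase gene Pygl at -1.80, Pgm2 at -1.49, Ppp1r3c with a fall of at least 1.36-fold and Ppp1r3d with at least 1.03-fold. Of 32 proteasome genes, 1 fell (adjusted over the list alone, 1 fell; adjusted p = 0.0262), Psmb7 at -0.91, and the list had adjusted p = 0.0700 with an estimated correlation (range 0.00170 to 0.0700). Psme1 had -0.71 (adjusted p = 0.142), Psma6 -0.70 (adjusted p = 0.293) and Psma4 -0.58 (adjusted p = 0.203). Of 30 interferon response genes, 0 passed over all probes or over the list alone (adjusted p = 0.0284), and the list had adjusted p = 0.0538 with an estimated correlation (range 0.000116 to 0.0538). Ifih1 had -0.62 (adjusted p = 0.0653), Tap1 an adjusted p of 0.0937, Gbp3 -0.82 (adjusted p = 0.135) and B2m 0.76 (adjusted p = 0.124), which had the opposite sign under median scaling. The other 14 of the 17 called lists kept their calls with an estimated correlation. Of the members named for these lists, Angptl4, Cox6a1, Eif4ebp1, Lpin1, Dsp, Pgm2, Atg3 and Rps19 had other probes that were not called, and Lpl and Fads2 had another probe called in the same direction.

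Of the fixed genes of insulin action, Pdk4 changed in diabetic mice. Pdk4 (probe mMC011321, chromosome 6, 5483351 to 5496278) fell at least 5.96-fold, from a mean log2 intensity of 9.01 ± 0.16 (SD, n = 3) to below the threshold (adjusted p = 0.000179). Insr was below the threshold on all diabetic mcIRBP arrays (adjusted p = 0.200). Slc2a4 had a log2 fold change of -0.22 (adjusted p = 0.935), Pik3r1 -0.72 (adjusted p = 0.0971) and Akt2 -0.57 (adjusted p = 0.388). Hk2 had 0.093 (adjusted p = 1.0), with the opposite sign under median scaling, and Irs1 and Ppargc1a were below the threshold on all 6 arrays. Of 48 insulin receptor signalling genes, 3 rose and 2 fell (adjusted over the list alone, 5 and 2; camera adjusted p = 0.427), and of 27 genes of GLUT4 traffic and glucose uptake 1 rose and 2 fell (adjusted over the list alone, 3 and 3; camera adjusted p = 0.310). In all, 2025 probes were called, 1114 higher and 911 lower, and 4576 had an unadjusted p under 0.05. The count was 4050 under median scaling, with 783 higher and 3267 lower, 4213 in a fit of these 6 arrays alone (1724 higher, 2489 lower), 6954 with array weights (3249 higher, 3705 lower), 3956 with the deposited normalized intensity (1861 higher, 2095 lower), and 1322, 1277 and 1301 without diabetic mock replicate 1, 2 and 3. Falls also outnumbered rises with the filter on dim probes (978 higher, 1039 lower) and without normal mcIRBP replicate 2 (1286 and 1299).

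**Figure D3:**
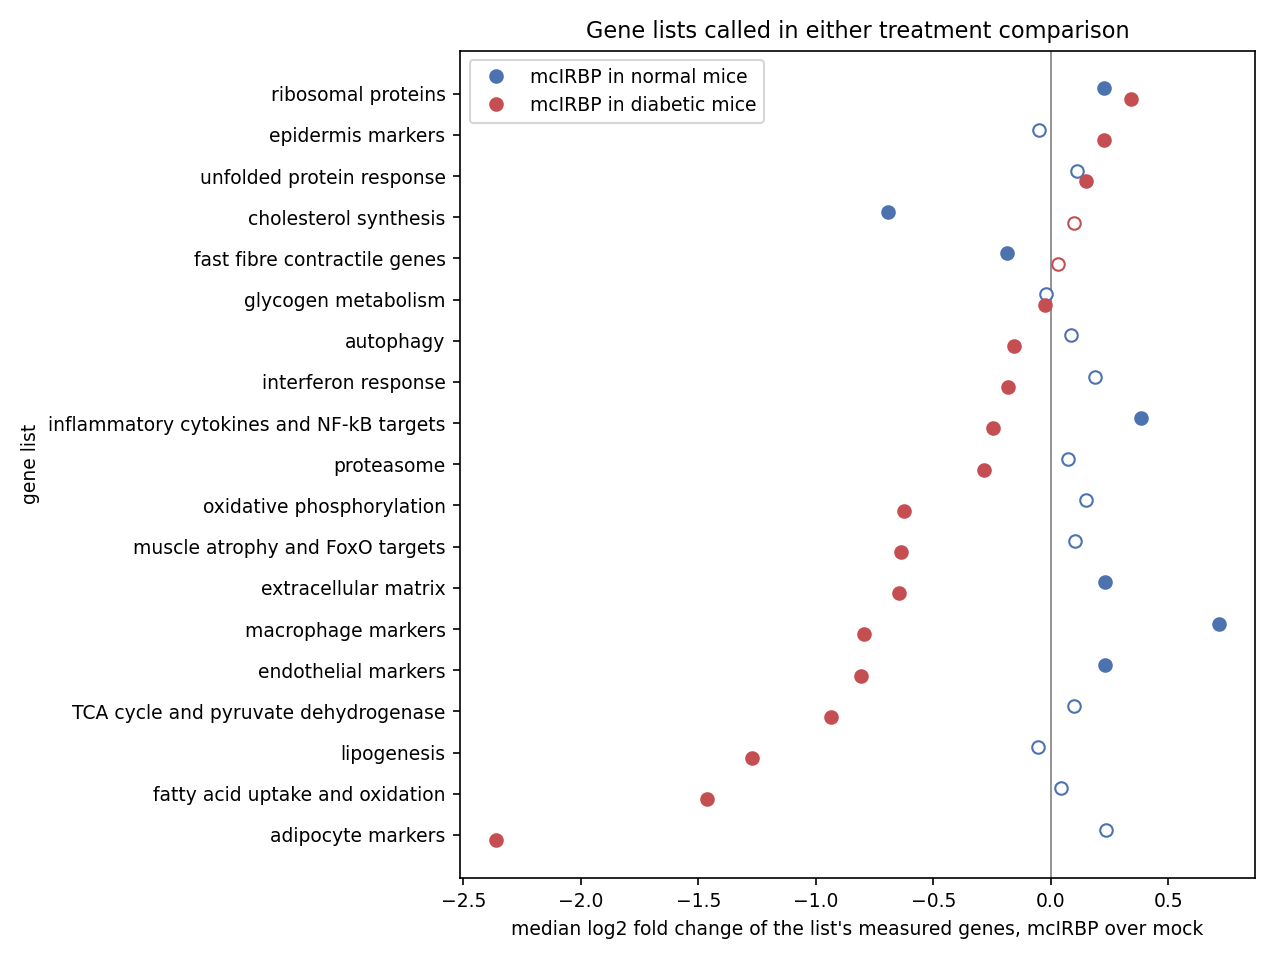
Median fitted log2 fold change (mcIRBP over mock) of the measured genes of each list called in normal mice (blue) or diabetic mice (red), filled where the list passed camera at an adjusted p under 0.05 and open where not. Adipocyte markers had the lowest median in diabetic mice (-2.36), and cholesterol synthesis the lowest in normal mice (-0.69).

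The difference between the effects in diabetic and normal mice asked whether mcIRBP acted differently in the 2 states. It was largest where one effect was large and the other near 0, and for some genes the effects ran in opposite directions. Clu, which encodes the secreted chaperone clusterin, had a log2 fold change of -2.19 in normal and 4.29 in diabetic mice, a difference of 6.48 (SE 0.88, adjusted p = 0.00101). It was among the 15 brightest genes of the diabetic mcIRBP arrays, as were the epididymis genes Defb20, Lcn8, Gpx5 and Lcn5. Whether its values follow the tissue content of the arrays was not tested. Cidec had 1.54 in normal and -3.76 in diabetic mice, a difference of -5.31 (SE 0.50, adjusted p = 8.82e-05), and Cav1 had 1.94 and -2.66, a difference of -4.60 (SE 0.25, adjusted p = 1.09e-06). Ttr fell in normal mice and was below the threshold on all diabetic arrays, with a fitted difference of 7.24 (adjusted p = 7.40e-08) and of 6.72 with groups below the threshold set to it. Defb20 was below the threshold on all normal arrays and had 5.90 in diabetic mice, a fitted difference of 6.04. The other large positive differences were of Apoa2, Ahsg, Hamp, Apoa1, Fabp1, Serpinc1 and Serpina1e, from 6.91 to 6.12 as fitted and from 5.64 to 6.56 with groups set to the threshold. The other large negative ones were of S3-12 with -5.14, Car3 with -4.88, Ephx2 with -4.23, the fat triglyceride lipase gene Pnpla2 with -4.22, AU018778 with -4.21, Adipoq with -4.13, Gsn with -4.13 and Serpina3c with -4.09. The calls of Pnpla2 and AU018778 ended with a block by replicate number. Among the fixed genes Pdk4 differed (fitted -3.60, set to the threshold -3.14, adjusted p = 0.000535), while Pik3r1 had -0.80 (adjusted p = 0.169), Akt2 -0.23 (adjusted p = 0.777) and Hk2 -0.24 (adjusted p = 0.550). Insr (adjusted p = 0.123), Slc2a4 (adjusted p = 0.467), Irs1 (adjusted p = 0.669) and Ppargc1a (adjusted p = 0.738) were below the threshold on all arrays of at least 1 group. In all, 2725 probes differed, 1277 with a more positive and 1448 with a more negative effect in diabetic mice, and 6311 had an unadjusted p under 0.05. Under median scaling the count was 6297, with 1403 positive and 4894 negative. Positive differences outnumbered negative ones on leaving out any 1 of the mock arrays or of the diabetic mcIRBP arrays, as with 1763 positive and 1689 negative without normal mock replicate 1. Of 67 liver markers 56 had a positive difference, of 36 epididymis genes 33, and 22 of 29 adipose tissue genes had a negative one. Of the genes that had not been seen, 33 of 44 liver markers and 14 of 17 epididymis genes had a positive difference. A negative one was found for 13 of the 19 adipose tissue genes that had not been seen.

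By list, 16 of the 34 differed between the states, 13 with a lower and 3 with a higher effect in diabetic mice. Members named here are given with groups below the threshold set to it. The effect on adipocyte markers was lower in diabetic mice for 8 of 13 genes and higher for 1 (adjusted over the list alone, 11 and 1; adjusted p = 4.64e-07). Members included Pck1 at -3.62 and Pparg at -2.30. It was lower for 13 of 33 extracellular matrix genes (adjusted over the list alone, 17; adjusted p = 2.45e-08). Members included Serpinh1 at -1.49, Sparc at -1.47, Col5a1 at -0.40 and Col15a1 at -0.13. It was also lower for 10 of 15 macrophage markers (adjusted over the list alone, 12; adjusted p = 1.39e-07). Members included Mrc1 at -2.87, Cd14 at -2.75, Lyzs at -2.15 and Cd163 at -0.0095. Of 35 fatty acid uptake and oxidation genes 15 had a lower effect and 1 a higher one (adjusted over the list alone, 17 and 1; adjusted p = 8.17e-07). Members included Angptl4 at -3.99, Lpl at -3.52, the fatty acid transporter gene Slc27a1 at -2.54 and Acsl1 at -2.15. The effect was lower for 8 of 32 genes of inflammatory cytokines and NF-kB targets (adjusted over the list alone, 16 lower and 1 higher; adjusted p = 3.02e-06). Members included Saa3 at -3.06 and Ccl2 at -2.06, while Tlr2 and Ptgs2 had 0. It was lower for 9 of 25 TCA cycle genes (adjusted over the list alone, 13; adjusted p = 9.18e-06). Members included Idh3g at -2.47, Cs at -2.42 and Idh3b at -1.44, while Dlat had 0. The same held for 8 of 63 oxidative phosphorylation genes (adjusted over the list alone, 12; adjusted p = 0.000198). Members included Sdhb at -2.53, Ndufs7 at -1.85, Ndufb9 at -1.76 and Cox8b at -1.49. Endothelial markers had a lower effect in 6 of 12 (adjusted over the list alone, 8; adjusted p = 1.25e-05). Members included Cldn5 at -2.07, Esam1 at -1.85 and Flt1 at -0.77, while Tek had 0.

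The effect on cholesterol synthesis was higher in diabetic mice for 8 of 17 genes and lower for 1 (adjusted over the list alone, 9 and 1; adjusted p = 6.55e-05), and under median scaling the adjusted p was 0.188 (range over the alternatives 4.92e-08 to 0.188). Members included Fdps at 4.71, Idi1 at 3.46, Tm7sf2 at 1.96 and Sc4mol at 1.90. The fitted median of the cholesterol list was -0.69 in normal and 0.10 in diabetic mice, and -0.85 for diabetic mock against normal mock. The effect was also higher for 4 of 12 epidermis markers (adjusted over the list alone, 4; adjusted p = 0.0118). Members included Perp at 2.70, Krt14 at 2.56 and Dsp at 1.20, while Krt15 was below the threshold on all 12 arrays. Muscle atrophy and FoxO targets had a lower effect in 9 and a higher one in 1 of 26 (adjusted over the list alone, 12 and 2; adjusted p = 0.000897). Members included Eif4ebp1 at -3.09, Gabarapl1 at -1.76 and the metallothionein gene Mt2 at -1.66. The interferon response had a lower effect in 3 of 30 (adjusted over the list alone, 8 lower and 1 higher; adjusted p = 0.00539). Members included Gbp3 at -1.70 and Ifih1 at -1.12, while Oasl1 had 0 and Gbp2 -1.04 (adjusted p = 0.0542). For 4 lists the call ended with an estimated correlation. Lipogenesis had 8 genes with a lower and 2 with a higher effect of 19 (adjusted over the list alone, 9 and 2; adjusted p = 0.0292) and had adjusted p = 0.129 with an estimated correlation (range 0.00106 to 0.129). Members included Fads2 at 2.67, Lpin1 at -2.88, Scd1 at -2.80 and Dgat1 at -2.13. Circadian clock genes had a lower effect in 5 of 18 (adjusted over the list alone, 6; adjusted p = 0.0237) and had adjusted p = 0.167 with an estimated correlation (range 0.000680 to 0.167). Members included Per2 at -1.14, Cry2 at -0.48 and Rora at -0.47, while Per1 had 0. Autophagy genes had a lower effect in 3 of 27 (adjusted over the list alone, 3; adjusted p = 0.0257) and had adjusted p = 0.0545 with an estimated correlation (range 0.000758 to 0.0606). Members included Bnip3 at -0.78 and Ulk1 at -0.30, while Ulk2 had an adjusted p of 0.0880. Fast fibre genes had a higher effect in 3 of 15 (adjusted over the list alone, 4 higher and 1 lower; adjusted p = 0.0326) and had adjusted p = 0.282 with an estimated correlation (range 0.00553 to 0.940). Members included Mylpf at 1.04, Atp2a1 at 0.78 and Mybpc2 at 0. As fitted, Mybpc2 and the fast fibre list as a whole had the opposite sign under median scaling, while Myl1 had an adjusted p of 0.0665. Other probes of Angptl4, Eif4ebp1, Lpin1, Ptgs2, Pck1 and Dsp were not called for the difference, and those of Car3, Lpl and Fads2 were called in the same direction.

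The mean of both effects asked what mcIRBP changed on average in the 6 treated against the 6 mock arrays. In limma 1958 probes were called, 1148 higher and 810 lower, and 5126 had an unadjusted p under 0.05. Of the 34 lists 9 were called, of which 7 stayed under the threshold with an estimated correlation. Muscle atrophy and FoxO targets then had adjusted p = 0.0538 and the unfolded protein response adjusted p = 0.144. The 9 included fatty acid uptake and oxidation, with 12 lower and 1 higher of 35 (adjusted over the list alone, 20 and 1; camera adjusted p = 4.47e-08), and adipocyte markers, with 8 lower of 13 (adjusted over the list alone, 11; adjusted p = 2.58e-07). They also included cholesterol synthesis, with 7 lower of 17 (adjusted over the list alone, 8 lower and 1 higher; adjusted p = 0.00106), and ribosomal proteins, with 6 higher of 22 (adjusted over the list alone, 8; adjusted p = 0.000531). Fitted medians in normal and diabetic mice were 0.044 and -1.46 for fatty acid uptake and oxidation and 0.24 and -2.36 for adipocyte markers. They were -0.69 and 0.10 for cholesterol synthesis and 0.23 and 0.34 for ribosomal proteins. Of these lists only the ribosomal proteins had fitted medians of the same sign in both states. With groups below the threshold set to it, theirs were 0 in normal and 0.34 in diabetic mice. Diabetic mock against normal mock, without mcIRBP, gave a fitted ribosomal median of 0.24. The unfolded protein response had fitted medians of 0.11 in normal and 0.15 in diabetic mice (0 and 0.27 set to the threshold). Under median scaling 820 probes were called, 265 higher and 555 lower, so that the balance of direction turned. Across all 29922 probes the effects in normal and diabetic mice had r = -0.0898, where simulated unchanged groups gave a mean r near 0 with a range of -0.0362 to 0.0368. Genes are not independent replicates, so this r has no p-value. The simulation drew each probe independently, while deviations of real arrays correlated across probes with r from -0.419 to 0.505. The simulated range is therefore too narrow to judge the observed r by. Of the called probes 60 rose in both states and 49 fell in both, against 38.5 and 24.7 for independent lists, while 169 rose in normal and fell in diabetic mice and 88 did the reverse, against 31.5 and 30.2.

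The comparison of diabetic mock with normal mock mice asked how the untreated states differed. Genes of the liver were lower on the diabetic arrays, and genes of the epididymis were higher. Ttr was at least 132-fold lower (adjusted p = 3.59e-09), and Alb fell from 13.77 ± 0.07 to 6.51 ± 0.06 (log2 intensity, SD, n = 3), a log2 fold change of -7.26. Gpx5, an epididymal glutathione peroxidase (probe mMC004874, chromosome 13, 21286429 to 21292727), was at least 4.44-fold higher (adjusted p = 3.27e-07). Cd74, the invariant chain of MHC class II, had a log2 fold change of 2.88 (SE 0.54, adjusted p = 0.0102), and H2-Ea, an MHC class II chain, 2.65. The other large falls were of Apoa2 by at least 116-fold, Hamp by at least 75.8-fold, Serpinc1 by at least 66.3-fold and Fabp1 by at least 62.4-fold, and of Apoa1 with a log2 fold change of -6.49, Ahsg with -6.35, Apoc3 with -6.17 and Serpina1e with -6.14. The other large rises were of Lcn8 by at least 2.76-fold, Lcn5 by at least 2.54-fold, Spink8 by at least 2.52-fold, the sodium channel gene Scn7a by at least 2.49-fold and 9230104L09Rik by at least 2.31-fold, and of Mt4 with a log2 fold change of 2.61 and Steap4 with 2.55. The calls of Cd74 and H2-Ea ended with a block by replicate number, and those of Mt4 and Steap4 ended under 9 of the alternatives each. Another probe of Scn7a was not called (adjusted p = 0.154). Insr passed (adjusted p = 0.0357) without a fold, with all 3 normal mock arrays below the threshold, and Pdk4 had a log2 fold change of 2.35 (SE 0.31, adjusted p = 0.00131). Slc2a4 (adjusted p = 0.819), Irs1 (adjusted p = 0.215) and Ppargc1a (adjusted p = 0.258) were below the threshold on all normal mock arrays. Pik3r1 had 0.36 (adjusted p = 0.319), Hk2 0.11 (adjusted p = 0.657) and Akt2 -0.14 (adjusted p = 0.780), which rose by 1.35 under median scaling (adjusted p = 0.00725).

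In the same comparison 3 of the 34 lists were called. Of 17 cholesterol synthesis genes 8 fell and 0 rose (adjusted over the list alone, 10 fell; camera adjusted p = 5.26e-06), and under median scaling the adjusted p was 0.364 (range over the alternatives 4.63e-08 to 0.364). Members included Idi1 at -2.75, Fdps at -2.30, Tm7sf2 at -1.52 and Sc4mol at -1.37. Of 15 macrophage markers 6 rose and 0 fell (adjusted over the list alone, 8 rose; adjusted p = 5.26e-06) and had adjusted p = 0.132 with an estimated correlation (range 4.62e-07 to 0.132). Members included Cd14 at 1.86, Cd68, which rose at least 1.5-fold, and Emr1 and Cd163 without a fold. Of 63 oxidative phosphorylation genes 5 rose and 0 fell (adjusted over the list alone, 6 rose and 1 fell; adjusted p = 0.00330) and had adjusted p = 0.132 with an estimated correlation (range 1.34e-06 to 0.132). Members included Cox5a at 2.26, Cox4i1 at 1.61, Ndufb9, which rose at least 2.31-fold, and Ndufs1 without a fold. In all, 2510 probes were called, 1367 higher and 1143 lower, and 7722 had an unadjusted p under 0.05. On the same arrays 60 of 67 liver markers fell and 0 rose, and 18 of 36 epididymis genes rose and 0 fell. Of the genes that had not been seen, 37 of 44 liver markers fell and 0 rose, and 3 of 17 epididymis genes rose and 0 fell. Falls outnumbered rises with array weights (620 higher, 1085 lower), without normal mock replicates 1, 2 and 3 (1581 and 1941, 950 and 1379, 1030 and 1557) and without diabetic mock replicates 1 and 3 (511 and 596, 526 and 607). The count was 15092 under median scaling (10073 higher, 5019 lower), 1053 with a block by replicate number, and 1107, 1398 and 1133 without diabetic mock replicate 1, 2 and 3, and the contrast cannot be told apart from the sex of the mice.

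Another 14 lists were called neither for mcIRBP in either state, nor for the difference, nor between the mock groups. Their lowest camera adjusted p over these 4 comparisons was 0.0726 for slow fibre genes, 0.0931 for antioxidant and NRF2 targets, 0.0936 for GLUT4 traffic and glucose uptake, 0.103 for immediate early genes and for neutrophil markers, and 0.107 for glycolysis. It was 0.121 for insulin receptor signalling, 0.143 for lymphocyte markers, 0.150 for myogenic and denervation genes, 0.155 for smooth muscle and pericyte markers, 0.347 for Y-linked genes, 0.502 for heat shock proteins, 0.566 for the cell cycle and 0.649 for nerve and Schwann cell markers.

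Whether mcIRBP moved the diabetic arrays toward the normal mock arrays was described across all probes. The effect in diabetic mice and the disease contrast share the diabetic mock arrays with opposite sign and had r = -0.106 (covariance -0.0226), where simulated groups without any effect gave a mean r of -0.499 (covariance -0.0164). The effect in normal mice and the disease contrast share the normal mock arrays and had r = 0.822 (covariance 0.168), where the simulation gave 0.501 (covariance 0.0165). The simulation gave every array the same spread per probe. The median SD over all probes was 0.038 on the diabetic mock arrays and 0.063 to 0.148 in the other groups. The simulated covariance for the shared diabetic mock arrays is therefore likely too far from 0. It cannot show how much of the observed value the shared arrays give. Of the called probes 398 were higher and 688 lower both on the normal mcIRBP and on the diabetic mock arrays than on the normal mock arrays, against 47.2 and 31.0 for independent lists. In diabetic mice 102 probes rose with mcIRBP and were lower in diabetic mock mice, and 307 fell and were higher, against 42.6 and 41.6. These overlaps share control arrays, and the 3 controls per group were not divided between the comparisons. The values for independent lists do not allow for the sharing, so part of the excess can come from the shared controls.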

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

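The interaction, mean-effect and list tests and the counts over other splits of the arrays were planned before the data were examined, and the tests of tissue, signal and regulation were chosen after the results they bear on had been seen. The difference between the mcIRBP effects in diabetic and normal mice, tested as an interaction in limma, passed the threshold for 2725 probes. In 100 drawn regroupings of the arrays within disease state, 1 gave a count as large, which was the real one. The highest of the others drawn was 1053, so a count this large was tied to the real grouping of these arrays. The labels do not say whether the arrays of a group came from different mice. If they were repeats of 1 extract, a chance difference between extracts would also give the real grouping the highest count. The regroupings therefore cannot exclude chance differences between animals or extracts. For the mean effect 1 of the 100 drawn gave a count as large, again the real one, with 1958 probes against a highest other drawn count of 1087. The draw was made from 200 regroupings and missed the 1 that exchanges the mock and mcIRBP labels within 1 state, which turns the mean effect into the difference and gives 2725. For the difference the same exchange gives 1958. Over all 200, counted after these results had been seen, the mean effect therefore had 2 counts as large and the difference had 1, the real one. Within 1 disease state 6 arrays give 10 splits, too few for a share under 0.05. In normal mice 1 of the 10 splits gave as many calls as the real 1845 (highest other 30), in diabetic mice 1 of 10 (2025, highest other 0), and for diabetic mock against normal mock 1 of 10 (2510, highest other 0).

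The first pattern is the fall of liver genes on the arrays labelled normal mcIRBP, seen in the differences of effects of Ttr (7.24), Apoa2 (6.91), Ahsg (6.4), Hamp (6.39), Apoa1 (6.36), Fabp1 (6.26), Serpinc1 (6.23) and Serpina1e (6.12). Regulation by mcIRBP within skeletal muscle is argued against as the whole cause, since 2.38% of the skeletal muscle genes were above the threshold on all 3 normal mock arrays. Fewer probes with signal on the treated arrays are argued against, since the number of probes above the threshold was 2.32 times that of the mock arrays. Liver RNA in the arrays labelled normal mock is a candidate explanation: of the liver list genes that had not been seen among the largest changes, 70.5% were above the threshold on all 3 of these arrays, against at most 18.2% in another group. Of its 67 genes, 23 had been seen, 0 were on the adipose list, Alb and Ttr were among the 15 brightest genes of these arrays, and a mix-up of samples and liver tissue in the extract cannot be separated with these data.

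The second pattern is the rise of epididymis genes on the arrays labelled diabetic mcIRBP, seen in the difference of effects of Defb20 (6.04). A general gain in signal is argued against, since probes above the threshold numbered 0.603 times those of the mock arrays, and regulation within skeletal muscle is argued against as the whole cause, since 4.76% of the skeletal muscle genes were above the threshold on all 3 diabetic mcIRBP arrays and at most 14.3% on a single one (21.4% on all 3 diabetic mock arrays). Epididymal RNA in the diabetic arrays is a candidate explanation: 76.5% of the epididymis genes not seen before were above the threshold on all 3 diabetic mcIRBP arrays, against 0% on the normal arrays, which were labelled female. Over the 25 epididymis genes above the threshold on all 6 diabetic arrays, intensities above the floor correlated between the groups across genes with r = 0.876 and differed by a median log2 ratio of 4.74 (SD 0.67), as 1 source at different shares could give. Of the 36 genes 19 had been seen before and 0 were on another list, Defb20, Lcn8, Gpx5 and Lcn5 were among the 15 brightest genes of the diabetic mcIRBP arrays, and a real change in the epididymis with mcIRBP stays open and untested.

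The third pattern is the fall of adipocyte genes on the arrays labelled diabetic mcIRBP, seen in the differences of effects of Cidec (-5.31), S3-12 (-5.14), Car3 (-4.88), Pnpla2 (-4.22) and Adipoq (-4.13), and of the adipocyte list (median -2.52). The housekeeping median exceeded that of the adipocyte markers by 2.29 (95% bootstrap interval over genes 1.21 to 2.89, log2). Quantile normalization removes a loss shared by all genes, so this value cannot decide on such a loss. The median raw intensity of housekeeping genes was 10.5 to 26.4 times the floor on diabetic mock and 2.65 to 8.02 times on diabetic mcIRBP arrays. For adipose tissue genes it was 43.4 to 114 and 1.53 to 3.74 times. This larger fall argues against an equal loss in all genes as the whole cause. A lower share of adipose tissue RNA is a candidate explanation, since macrophage, endothelial and extracellular matrix genes fell with the adipocyte markers, the least of their medians being -0.65 (-0.28 with groups below the threshold set to it). The smooth muscle and pericyte, lymphocyte and neutrophil lists were not called (camera adjusted p = 0.611, 0.143 and 0.910). Of 12 lymphocyte markers 2 were above the threshold on all 3 diabetic mock arrays, so few could fall. For smooth muscle and pericyte markers 7 of 12 were above it on all 3 diabetic mock and 3 on all 3 diabetic mcIRBP arrays. For neutrophil markers these counts were 7 and 3 of 10. An effect of mcIRBP on the expression of adipocyte genes (list median -2.36) cannot be told apart from a lower share of adipose tissue RNA, because the treatment and the change in tissue markers fall on the same arrays. Of the 29 genes of the adipose tissue list 21 are on lists written before the data were examined.

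Further genes differed between the effects in the same test, given here as fitted log2 differences. With groups below the threshold set to it, the fitted median difference of liver genes of 3.45 was 2.86, that of epididymis genes of 4.35 was 4.28, and that of adipocyte markers was -2.30. Set in the same way, the medians below were 0 for the circadian clock and epidermis lists, -0.035 for the interferon response, -0.097 for autophagy, -0.15 for inflammatory genes, -0.62 for endothelial markers, -0.70 for extracellular matrix and -0.84 for macrophage markers. Clu had 6.48, Cav1 -4.60, Ephx2 -4.23, AU018778 -4.21, Gsn -4.13, Serpina3c -4.09 and Pdk4 -3.60. The median differences of lists of energy and lipid metabolism were -1.26 for fatty acid uptake and oxidation, -0.73 for the TCA cycle and pyruvate dehydrogenase, -0.62 for oxidative phosphorylation, -0.79 for lipogenesis and 0.95 for cholesterol synthesis. For cell type and matrix lists they were -1.70 for macrophage markers, -1.11 for endothelial markers, -0.97 for extracellular matrix and 0.12 for epidermis markers. The remaining medians were -0.75 for inflammatory cytokines and NF-kB targets, -0.55 for muscle atrophy and FoxO targets, -0.50 for the interferon response, -0.29 for the circadian clock, -0.29 for autophagy and 0.31 for fast fibre contractile genes.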

How the results depend on the processing

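Alternatives named as added were chosen after the data had been seen, and where a result moved the cause was not tested unless stated. The probes called in normal mice numbered 292 under median scaling (31 higher, 261 lower), 1012 with the deposited normalized intensity, 616 with array weights (145 higher, 471 lower), 1185 with a block by replicate number and 520 in a fit of the 6 arrays alone (152 higher, 368 lower). In diabetic mice they numbered 4050 under median scaling (783 higher, 3267 lower), 3956 with the deposited normalized intensity, 6954 with array weights and 4213 in a fit of the 6 arrays alone (1724 higher, 2489 lower). Over 1491 probes above the threshold on all arrays the median SD was 0.247 and 0.558 on the normal and 0.114 and 0.210 on the diabetic arrays, and the array weights ran from 0.245 to 0.566 and from 0.546 to 5.90. Under median scaling the difference of effects had 6297 calls (1403 positive, 4894 negative), the mean effect 820 (265 higher, 555 lower) and the mock comparison 15092 (10073 higher, 5019 lower). The mock comparison had 1053 with the block. Leaving out 1 array at a time gave 1406 to 2813 in normal mice (2813 without normal mock replicate 1), 1277 to 2585 in diabetic mice (1322, 1277 and 1301 without diabetic mock replicates 1, 2 and 3), 1904 to 3452 for the difference, 1352 to 2476 for the mean and 1107 to 3522 for the mock comparison (1107, 1398 and 1133 without the same 3 arrays). Without background correction no count moved by over 1.5 times. The added fit without 2 arrays gave 1889, 2281, 2919, 2151 and 3432 calls for the 5 comparisons in this order, and the added fit without liver, epididymis and adipose genes 1745, 1936, 2578, 1806 and 2344. The added filter gave 1560, 2017, 2583, 1827 and 1765, and the medians of the probes it kept were 0.15 in normal mice, -0.064 in diabetic mice, -0.20 for the difference and 0.18 for the mock comparison.

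The correlation of both mcIRBP effects was -0.516 under median scaling, -0.104 without the tissue genes and -0.113 to -0.0700 without 1 array. The covariance with the mock comparison was -0.269 under median scaling, -0.0512 with the filter, -0.0275 without the tissue genes and -0.0254 to -0.0205 without 1 array. The fitted log2 difference of Eif2s3y was 1.61. With the deposited normalized intensity it was 1.30, which is not a like comparison, since the states had been normalized apart. Of 43 list calls outside the mean effect 29 held with an estimated correlation, fry gave 82 calls, and leaving out 1 array gave 38 to 47. In normal mice the ribosomal (adjusted p 0.0541 to 0.136), endothelial (0.0541 to 0.269) and fast fibre (0.0541 to 0.164) calls each ended without normal mock replicate 1, normal mcIRBP replicates 1 and 3 or diabetic mcIRBP replicates 1 and 3. Normal mock replicate 2 also ended the ribosomal and endothelial calls, replicate 3 the ribosomal and fast fibre calls, and normal mcIRBP replicate 1 that of extracellular matrix (0.146). The proteasome call in diabetic mice ended without diabetic mcIRBP replicate 3 (0.0569), and calls of the difference ended for lipogenesis and the circadian clock without normal mock replicate 2 (0.0651 and 0.0617). Calls of the difference also ended for autophagy without normal mock replicate 1, normal mcIRBP replicates 1 and 3 or diabetic mcIRBP replicate 3 (0.0514 to 0.0606), and for fast fibre genes without normal mock replicates 1 and 3, normal mcIRBP replicate 3 or diabetic mcIRBP replicate 3 (0.0581 to 0.114). In the added fit without 2 arrays autophagy and the proteasome had 0.0632 and 0.0692 in diabetic mice, and fast fibre genes 0.0762 in the difference.

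Signs turned under median scaling for Akt2 in normal mice (0.36) and between the mock groups (1.35), for Rpl22 (-0.21), Rpl31 (-0.032), Dnajb9 (-0.11), B2m (-0.25), Irs1 (0.065), Hk2 (-0.91) and Ppargc1a (0.042) in diabetic mice, for Mybpc2 in the difference (-0.38), and for the fast fibre list in the difference (signed -log10 adjusted p of -0.027). In the added fit without 2 arrays Akt2 had 0.052 in normal and Hk2 -0.022 in diabetic mice. Without 1 array the log2 values ran in normal mice from -0.24 to 0.017 for Irs1, -0.21 to 0.23 for Pik3r1, -0.55 to 0.051 for Akt2 and -0.23 to 0.0046 for Ppargc1a, and in diabetic mice from -0.023 to 0.16 for Hk2 and -0.040 to 0.00029 for Ppargc1a. In the difference they ran from -0.021 to 0.23 for Irs1 and -0.021 to 0.22 for Ppargc1a, and between the mock groups from -0.12 to 0.27 for Slc2a4 and -0.28 to 0.0067 for Akt2. Replicate numbers did not pair the arrays: deviations of arrays with the same number correlated across probes with r between -0.344 and 0.247, and those with other numbers between -0.419 and 0.505. The filter on flags was not run, nor was a block by slide or scan date, since the files give none. The deposited normalized intensity was not used for the mock comparison.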

Other observations

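Genes of digestive enzymes of the pancreas and genes of maturing sperm were higher on the diabetic mcIRBP arrays than on the diabetic mock arrays. Of 16 pancreas genes, 0 were above the threshold on all 3 arrays of either normal group, 10 on all 3 diabetic mock arrays and 12 on all 3 diabetic mcIRBP arrays, and 12 rose with mcIRBP and 0 fell, with a median log2 fold change of 2.37. In limma the trypsin gene Prss2 had a log2 fold change of 3.82 (SE 0.12, adjusted p = 2.43e-08), the lipase genes Pnliprp1 and Pnlip had 3.68 and 3.54, and the chymotrypsinogen gene Ctrb1 had 3.42. The islet hormone genes Ins2 and Gcg were not called and were below the threshold on all 12 arrays. Of 24 genes of testis and sperm, 4 were above the threshold on all 3 diabetic mock arrays and 11 on all 3 diabetic mcIRBP arrays, and 11 rose and 0 fell. Prm1 and Prm2, the protamines that pack sperm DNA, rose, Prm1 with a log2 fold change of 4.0 (adjusted p = 3.46e-10) and Prm2 at least 9.05-fold (adjusted p = 7.55e-10). These genes were chosen after their values had been seen.

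Of 42 skeletal muscle genes 7 fell and 0 rose with mcIRBP in normal mice, 1 rose and 1 fell in diabetic mice, and 10 were lower and 0 higher in diabetic mock than in normal mock mice. By detection the mock groups differed the other way. Of the 42 genes 9 were above the threshold on all 3 diabetic mock arrays and 1 on all 3 normal mock arrays. The fitted differences near the floor therefore do not settle the direction for muscle genes as a set. The muscle creatine kinase gene Ckm had a log2 fold change of -0.81 in normal mice (adjusted p = 0.000109), where it was above the threshold on 2 of 3 arrays of each group. Its raw intensity was 83 to 138 on the normal mock and 73 to 131 on the normal mcIRBP arrays. These ranges overlap near the floor, so the fitted fall may rest on the normalization. Ckm was below the threshold on all diabetic arrays and at least 2.29-fold lower in diabetic mock than in normal mock mice (adjusted p = 1.19e-06). The skeletal actin gene Acta1, above the threshold on 2 of 3 diabetic mock arrays, had a log2 fold change of -1.80 between the mock groups (adjusted p = 0.00299). Its raw intensity was 51 to 77 on diabetic mock arrays, whose floors were 39.6 to 39.7. On normal mock arrays it was 112 to 141, with floors of 56.8 to 94.5, so part of this difference may come from the floors.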
